A study of Mus musculus with 10 samples.

How the data were processed

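The data are RNA sequencing libraries of NIH3T3 cells, an established line of mouse embryo fibroblasts. There are 10 libraries: 1 of parental cells, 1 of cells stably carrying the empty vector, 4 of clones stably overexpressing FOXP2 and 4 of clones stably overexpressing FOXP2-CPED1. Per the labels' protocols, RNA was extracted with Trizol and libraries were made from 1 µg of total RNA with the NEBNext Ultra RNA kit. Per the series' design text, the clones of each construct are independent, and the parental and vector cells are the controls. Each clone, and each control, was measured in 1 library, so the spread within a construct is the spread between clones. The labels do not say that the vector cells are a clone, and nothing in them says when each culture was grown or sequenced.

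The authors deposited 1 table of RPKM values (read counts scaled by transcript length and by the mapped reads of the library) with a column per library, per the file headers. Reads were aligned with HISAT2 and assembled or quantified with StringTie, with mm9 as the genome, per the submitters' processing notes. Tool versions, the gene annotation, the strand setting and any filter are not given in the sources used here. The table has 18430 rows. Of these, 3581 name no gene and hold 3.37 to 4.54% of the summed RPKM of a library; they were left out of the tests. A further 976 rows join several genes in 1 locus, and their value cannot be assigned to a single gene. For 572 symbols the table has several rows, and the row with the highest mean carried the symbol. Pseudogenes, members of gene families and overlapping or antisense genes can share reads with their copies, so their values are uncertain.

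RPKM values are not counts, so no count model was used. Steps among values under 0.3 RPKM gave the relative depth of the libraries, from 0.913 to 1.32 of the parental library, while the absolute depth is unknown and no counting interval was computed. An exact 0 in this table can be a failed estimate, so such a gene is described as listed at 0.

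Values were transformed as log2(RPKM + 1). A row was tested if it named a gene and reached 1 RPKM in at least 2 of the 10 libraries, which left 12842 rows. A linear model with 3 arms (control, FOXP2 and FOXP2-CPED1) was fitted to all 10 libraries with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a trend on the mean. The control arm holds the parental and the vector library. All p-values of single genes are two-sided and from limma, with Benjamini-Hochberg adjustment within a comparison and 0.05 as the threshold. Fold changes are on the log2(RPKM + 1) scale and understate the change of genes with low values. Errors of levels are SDs between libraries, and errors of log2 fold changes are standard errors from the model. The p-values measure the spread between these cultures.

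Groups of genes were tested with camera from limma, with a preset correlation of 0.01, on those of 34 lists of pathway, cell state and cell type genes that had at least 5 measured members (32 lists), and the p-values were adjusted over the lists within a comparison. Each result is given with the p from camera with an estimated correlation between members, and with the count of members that pass when the adjustment is made over the list alone. Another test, fry, asked whether a list's genes moved on balance in 1 direction, without comparing them with other genes.

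The lists, the groups, the tests, the rule for named genes and most alternatives were fixed before the data were examined. Named genes were Foxp2 and Cped1 and, per comparison, the 10 largest rises and the 10 largest falls among genes past the threshold whose libraries did not overlap between the arms and whose mean reached 2 RPKM in an arm. Symbols that are only clone or model names and small RNAs were left out of this rule. Where fewer than 5 genes passed in a direction, the 5 with the smallest p in it were added. From each list called by camera, and from up to 6 further lists with members past the threshold, the 4 members with the smallest p were taken. Of the genes that these rules take, 1 is not reported here. Of the 13862 single-gene IDs, 13803 (99.6%) matched a mouse annotation on a later genome build than mm9 (GRCm38). It was used only for gene class, chromosome, order along the chromosome, and transcript length and GC content, so no coordinates are given.

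The alternatives were pseudocounts of 0.1 and 0.25, no filter, a filter on a mean of 5 RPKM, quantile normalization, scaling by median ratios, a fit without the trend, library quality weights, a fit of only the arms compared, clone numbers as a block, and each library left out in turn. Further alternatives, chosen after seeing the data, were adding the rows that name no gene, using only rows of single protein-coding genes, adding joined rows to the lists, and leaving out the 3 libraries with mitochondrial rows at 0. A comparison of all 8 clones with the control was also added then.

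The steps were tested on simulated data with the means and spreads of the 12842 tested rows, with 200 genes changed in each of 5 simulations. The changed genes were drawn only from rows with a mean log2(RPKM + 1) of at least 2. The recovered shares therefore do not cover genes with lower values. Each gene had the same spread in every library. For FOXP2 against control, 46.3% of genes changed by 1 on the log2 scale and 94.2% of those changed by 2 were recovered, with 6.2 false calls on average. For FOXP2-CPED1 against control these values were 50.7%, 91.2% and 5.6, and between the constructs 69.0%, 95.5% and 5.6. A list shifted by -0.7 in the FOXP2 arm was recovered in 5 of 5 simulations, with 0 other lists called. Noise was drawn independently for each gene. The simulations therefore cannot show how often camera calls unchanged lists whose members are correlated. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.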

Results

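RNA was sequenced from 10 cultures of NIH3T3 cells, an established line of mouse embryo fibroblasts. The question was how overexpression of FOXP2, a forkhead transcription factor, or of FOXP2-CPED1, which the series calls an arrangement of FOXP2, changes their transcripts. There were 4 clones with FOXP2, 4 clones with FOXP2-CPED1, and 1 parental and 1 vector culture as the controls. The summed RPKM of a library ranged from 794682 in FOXP2-CPED1 clone 3 to 944602 in FOXP2-CPED1 clone 2, and 12696 to 13172 rows reached 1 RPKM. Relative depth, read from the steps of low values, lay between 0.913 and 1.32 of the parental library. Spearman correlations between libraries ran from 0.925 to 0.982, highest between parent and vector, and no pair of libraries was identical. Across tested genes, the median correlation was 0.953 between clones of the same construct and 0.959 between clones of different constructs. Both rows of mitochondrially encoded genes were listed at 0 in FOXP2 clone 2, FOXP2 clone 4 and FOXP2-CPED1 clone 3, and summed to 33213 to 41130 RPKM in the other 7 libraries. The first principal component held 27.4% of the variance and the second 19.4%. The controls lay at 24.0 (parent) and 32.5 (vector) on the second component, above all clones, which ran from -39.1 to 11.1. The first component spread the clones within both constructs, from -32.4 to 41.3 for FOXP2 and from -39.3 to 24.8 for FOXP2-CPED1.

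**Figure D1:**
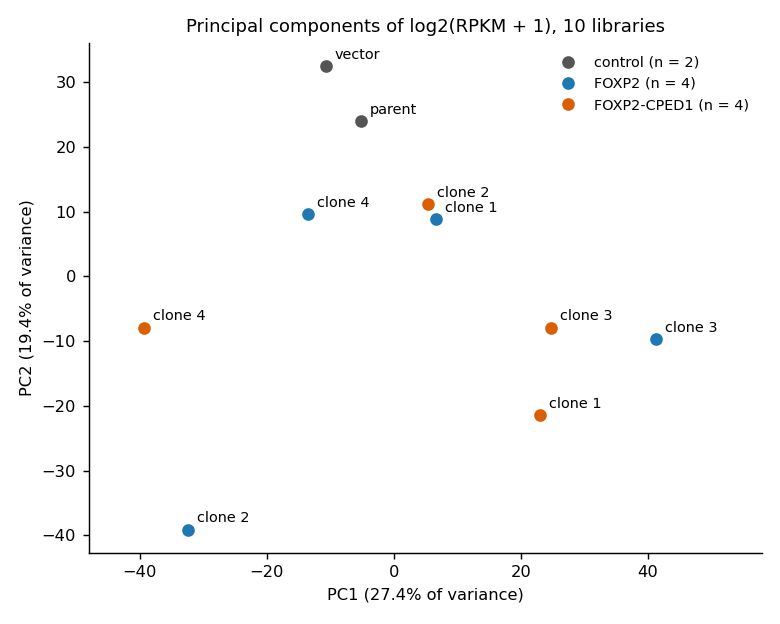
First and second principal components of log2(RPKM + 1) over the tested rows, with 1 point per library (2 controls, 4 FOXP2 clones, 4 FOXP2-CPED1 clones); axes give component scores. The 2 controls sit at the top of the second component (24.0 and 32.5), and the clones of both constructs are mixed along the first.

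The mouse row of Foxp2, the gene of the transcription factor itself, was low in every library. It stood at 0.0798 RPKM in parental and 0.0785 in vector cells. In FOXP2 clones 1 to 4 it was 0.217, 0.365, 0.145 and 1.02 RPKM, and in FOXP2-CPED1 clones 1 to 4 it was 0.161, 0.169, 0.0674 and 0.330. Means were 0.437 ± 0.400 (SD, n = 4) for FOXP2 and 0.182 ± 0.109 (n = 4) for FOXP2-CPED1, against 0.0791 ± 0.000933 (n = 2) in the control. Cped1, named for cadherin-like and esterase domains, stood at 25.6 ± 1.94 RPKM in the control, 19.9 ± 10.8 with FOXP2 and 17.6 ± 8.08 with FOXP2-CPED1. Its lowest values were 6.43 in FOXP2 clone 2 and 6.69 in FOXP2-CPED1 clone 4. The Foxp2 row reached 1 RPKM in 1 library and so failed the filter. Fitted by limma without the filter, it had adjusted p = 0.723 with FOXP2, 0.944 with FOXP2-CPED1 and 1 between constructs. Cped1 met the filter and did not pass, with adjusted p = 0.861, 0.872 and 0.9998 in the same order. Two-sided exact permutation tests gave p = 0.2 (FOXP2), 0.333 (FOXP2-CPED1) and 0.229 (between constructs) for Foxp2, and p = 0.667, 0.4 and 0.857 for Cped1. The smallest p these designs allow is 0.0667 against control and 0.0286 between constructs. The species and length of the introduced sequence are not given in the sources used here, so the mouse rows may miss it and do not check the labels.

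Parent and vector cells, the 2 controls, had 1 library each, so their difference has no replicate check and was not tested. Of 12842 rows, 198 were at least 2-fold higher and 98 at least 2-fold lower in vector than in parental cells. Across genes, which are not independent replicates, Pearson's r was 0.980 and Spearman's rho 0.982. Most gene lists moved little between the controls. Their medians on the log2 scale ran from -0.18 for skeletal muscle genes and -0.18 for blood and immune cell genes to 0.11 for imprinted genes. Smooth muscle contractile genes had a median difference of 0.02 and cholesterol synthesis genes one of 0.06. Cytosolic ribosomal protein genes had one of -0.145. That is about as large as their medians against the control, -0.13 with FOXP2 and -0.16 with FOXP2-CPED1. Among single genes, Foxn3, a forkhead repressor, stood at 123.0 RPKM in parental and 24.4 in vector cells.

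The first comparison asked what FOXP2 overexpression changes against the control. No control is stated to be a clone, so deriving or handling clones cannot be told apart from the construct in this or the next comparison. Most of what passed the test was lower in the clones: 51 genes fell and 5 rose. The deepest fall was in Thbs1, a secreted matrix glycoprotein, from 169.9 ± 13.6 RPKM (SD, n = 2) in the control to 10.8 ± 6.10 (n = 4). Several transcription factors also fell. Nr4a1, an orphan nuclear receptor, went from 315.8 ± 1.79 to 37.8 ± 31.7 RPKM, and the zinc finger factors Egr2 and Egr3 from 47.4 ± 2.98 to 6.86 ± 3.18 and from 51.9 ± 3.98 to 5.47 ± 4.00. Cpa6, a carboxypeptidase, rose from 0.175 ± 0.101 to 4.36 ± 1.75 RPKM.

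The log2 fold change was -4.03 ± 0.52 for Thbs1 (adjusted p = 0.0167, limma), -3.33 ± 0.52 for Nr4a1 (adjusted p = 0.0299), -3.29 ± 0.57 for Egr3 (adjusted p = 0.0443) and -2.73 ± 0.41 for Egr2 (adjusted p = 0.0250). Npas4, an activity-dependent transcription factor, fell from 10.7 ± 0.448 to 0.751 ± 0.583 RPKM, and Arc, which acts at synapses in neurons, from 8.92 ± 0.576 to 1.08 ± 0.405, both with adjusted p = 0.00262. F3, the tissue factor that starts blood clotting, fell from 433.3 ± 0.0481 to 73.3 ± 32.4 RPKM (adjusted p = 0.0167). Plau, the urokinase plasminogen activator, fell from 32.1 ± 0.687 to 4.33 ± 1.64 (adjusted p = 0.0401). Myl9, a regulatory light chain of myosin, fell from 27.6 ± 2.54 to 3.20 ± 1.37 RPKM (adjusted p = 0.0226). Foxn3 fell from 73.7 ± 69.7 to 6.13 ± 2.02 RPKM (adjusted p = 0.0424), with the 2 controls far apart. Each of these 10 genes was lower in 4 of 4 clones than in either control, which the rule for named genes requires. Besides Cpa6 (log2 fold change 2.14 ± 0.29, adjusted p = 0.0167), Sema3c, a secreted guidance protein, rose from 15.5 ± 2.70 to 54.0 ± 18.6 RPKM (adjusted p = 0.0475). Acly, which makes cytosolic acetyl-CoA for lipid synthesis, rose from 61.2 ± 2.99 to 116.5 ± 8.51 (adjusted p = 0.0342). The other risers, the predicted gene Gm16867 and the joined row Gm10033/Gm10311, were named after their values were seen. The next genes by p among the higher ones missed the threshold: the sterol demethylase Cyp51 stood at 43.6 ± 0.690 RPKM in the control and 116.0 ± 29.8 in the clones (adjusted p = 0.0884), and the transcription factor Tfap4 at 3.79 ± 0.478 and 8.76 ± 1.56 (adjusted p = 0.0895).

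In all, 56 of 12842 genes passed, 54 of them by at least 2-fold. An unadjusted p under 0.05 was reached by 1094 genes, where chance gives 642 on average. Such counts vary widely in these libraries: splits of the clones that mix the constructs gave 136 to 2989, so 642 is no firm bound. Values of the arms did not overlap for 19.5% of genes, against 13.3% if the libraries of both arms were interchangeable. Parent and vector were the most alike pair of libraries, so a larger share than 13.3% could be apart without any change. Among the 56 were 3 joined rows and 6 rows of symbols with several rows. The count was 2 without the parental library, 3 without vector, 22 without FOXP2 clone 1, 25 without FOXP2 clone 4, 33 without FOXP2-CPED1 clone 1, 29 without FOXP2-CPED1 clone 3, and 23 without the 3 libraries whose mitochondrial rows were at 0; without the parental library the log2 fold changes were still -4.11 for Thbs1 and -3.33 for Nr4a1, but -1.89 for Foxn3, whose value in the full fit was -3.03. The count was 9 in a fit of only the arms compared, 37 with a pseudocount of 0.1 and 2095 with library quality weights, which put 1013 higher and 1082 lower.

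**Figure D2:**
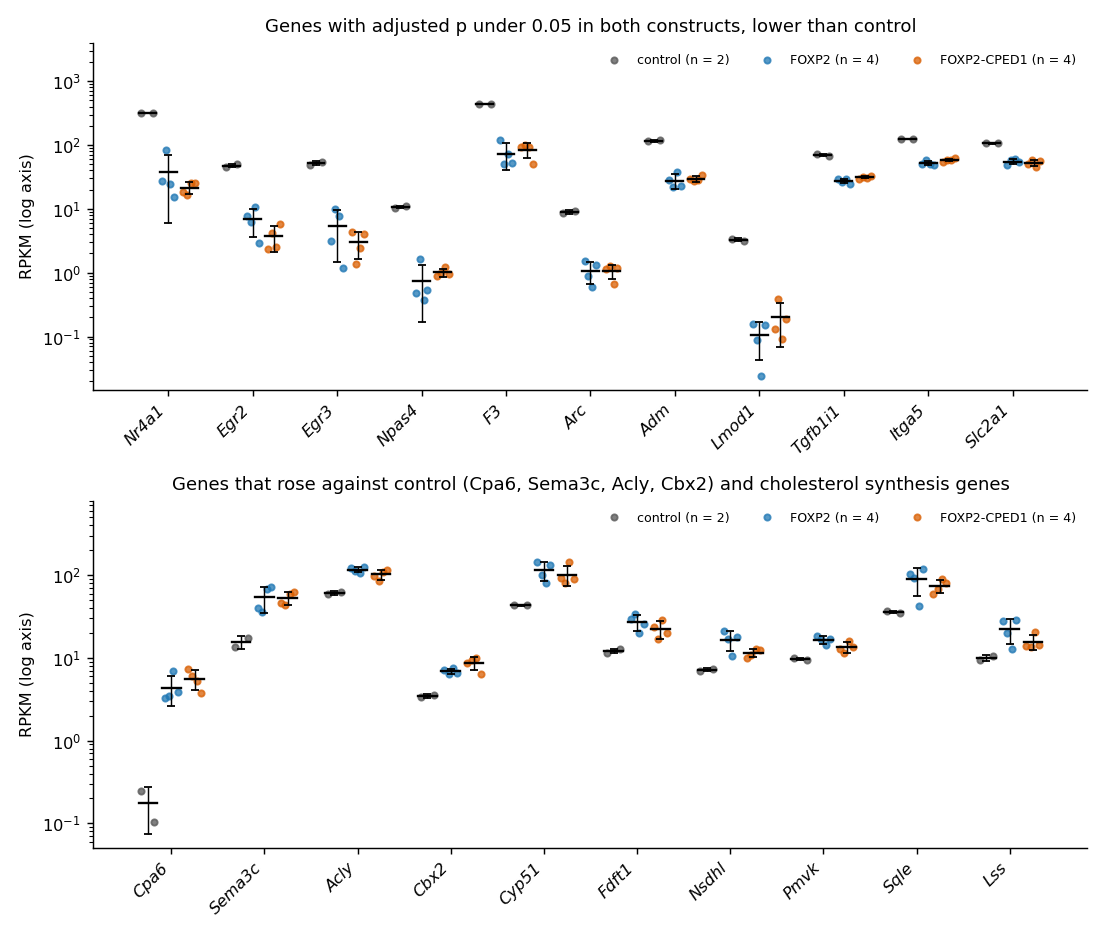
RPKM on a log axis of named genes in the control (n = 2), FOXP2 (n = 4) and FOXP2-CPED1 (n = 4) libraries, with points for libraries, a horizontal line for the mean and bars for the SD. In the upper panel, genes past the threshold in both constructs sit lower in all clones than in both controls. F3, for example, stood at 433.3 against 73.3 and 83.5. The rule for named genes requires this for Nr4a1, Egr2, Egr3, Npas4, F3 and Arc. The lower panel shows genes that rose in at least 1 construct and cholesterol synthesis genes, which were not called one by one.

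Smooth muscle contractile genes, TGF-beta response genes, YAP/TEAD targets and mesenchymal regulators were called lower with FOXP2 by camera with its preset correlation, calls that were lost with an estimated correlation (smallest adjusted p = 0.0758). Of 14 measured smooth muscle contractile genes, 2 fell (Lmod1 and Myl9), 12 did not pass, and all 14 had negative log2 fold changes (median -0.85). Lmod1, which nucleates actin filaments, went from 3.28 ± 0.166 to 0.106 ± 0.0632 RPKM (n = 2 and 4). The actin-binding protein Csrp1 stood at 70.2 ± 1.41 and 38.0 ± 7.70 and the actin Actg2 at 8.24 ± 0.724 and 1.05 ± 0.915, neither past the threshold. The list was called (camera adjusted p = 6.62e-13; adjusted p = 0.0846 with an estimated correlation), and 8 members were lower when adjusted over the list alone. Of 21 TGF-beta response genes, 1 fell: Tgfb1i1, a focal adhesion adaptor, from 69.9 ± 3.19 to 27.3 ± 2.29 RPKM. The secreted matrix protein Ctgf stood at 362.0 ± 16.9 in the control and 40.7 ± 24.2 in the clones without passing (adjusted p = 0.168). This list had a median of -0.62 (adjusted p = 1.18e-06; adjusted p = 0.0758 with an estimated correlation) and 2 lower members adjusted over the list alone. Of 16 YAP/TEAD targets, F3 and Amotl2 fell; Amotl2, a scaffold at cell junctions, went from 193.6 ± 4.77 to 88.1 ± 15.8 RPKM. Their median was -0.39 (adjusted p = 5.04e-06; adjusted p = 0.123 with an estimated correlation), and 7 were lower adjusted over the list alone. Of 18 mesenchymal regulators, the fibronectin receptor subunit Itga5 fell, from 124.9 ± 0.991 to 51.8 ± 3.74, while the filament protein Vim stood at 2967 ± 244.2 and 1763 ± 516.1 without passing. This list had a median of -0.28 (adjusted p = 0.00194; adjusted p = 0.0758 with an estimated correlation) and 1 lower member adjusted over the list alone.

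Cholesterol synthesis genes were called higher with FOXP2 with the preset correlation (camera adjusted p = 1.02e-14) but not with an estimated correlation (adjusted p = 0.199) or by fry (adjusted p = 0.0834). All 19 measured members had positive log2 fold changes (median 0.82), 0 passed singly by limma over all genes, and 12 were higher when adjusted over the list alone. The squalene synthase Fdft1 stood at 12.1 ± 0.765 RPKM in the control and 27.2 ± 5.96 in the clones, the sterol dehydrogenase Nsdhl at 7.21 ± 0.256 and 16.6 ± 4.46, and the kinase Pmvk at 9.65 ± 0.302 and 16.6 ± 1.71. Of 12 histone genes, 11 were on the higher side (median 0.52; adjusted p = 6e-04; adjusted p = 0.0758 with an estimated correlation). Among them 0 passed over all genes and 3 did when adjusted over the list alone; Hist1h4b stood at 1.59 ± 1.41 and 5.95 ± 3.84 RPKM. Amino acid and unfolded protein stress genes had a median of 0.33 with 21 of 24 on the higher side (adjusted p = 0.00532; adjusted p = 0.408 with an estimated correlation). In this list 0 passed either way; the chaperone Hspa5 stood at 244.1 ± 4.65 and 353.6 ± 86.3 and its partner Hyou1 at 23.8 ± 0.120 and 36.4 ± 4.60.

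Further lists were called lower, with 0 or 1 members past the threshold over all genes. The 16 NRF2 targets had a median of -0.52 (adjusted p = 2.02e-05; adjusted p = 0.348 with an estimated correlation), with 4 lower adjusted over the list alone; the heme oxygenase Hmox1 stood at 130.7 ± 5.44 in the control and 73.8 ± 11.2 in the clones, and the glutathione transferase Gstm1 at 313.0 ± 1.42 and 141.2 ± 46.7. The 19 cytokine, chemokine and NF-kB genes had a median of -0.59 (adjusted p = 0.00532; adjusted p = 0.534 with an estimated correlation), with 0 passing adjusted over the list alone; the inhibitor Nfkbia stood at 66.0 ± 4.74 and 34.6 ± 9.91. The 19 MAPK feedback genes had a median of -0.19 and the same pair of adjusted p-values, 0.00532 and, with an estimated correlation, 0.534. Of these, 3 were lower adjusted over the list alone, and the phosphatase Dusp5 stood at 87.5 ± 8.39 and 19.2 ± 16.3. The 18 p53 targets had a median of -0.17 (adjusted p = 0.0122; adjusted p = 0.534 with an estimated correlation), with 0 passing adjusted over the list alone; the antiproliferative Btg2 stood at 39.2 ± 0.397 and 13.4 ± 2.71. The 34 cytosolic ribosomal protein genes had a median of -0.13 (adjusted p = 0.00424; adjusted p = 0.676 with an estimated correlation), with 1 lower adjusted over the list alone; Rps29 stood at 864.2 ± 115.1 and 476.9 ± 32.4. Of 16 proteases and inhibitors, Plau fell, and the list had a median of -0.16 (adjusted p = 0.0309; adjusted p = 0.197 with an estimated correlation) with 2 lower adjusted over the list alone.

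Lists that were not called held a few changed genes. In hypoxia and glycolysis (24 measured, median 0.15, adjusted p = 0.723), Adm, a vasodilator peptide, fell from 116.1 ± 2.81 to 27.6 ± 7.0 RPKM, and the glucose transporter Slc2a1 from 105.7 ± 0.409 to 55.0 ± 5.26, while the glycolytic kinase Pgk1 stood at 495.9 ± 13.2 and 766.1 ± 221.2; 2 were lower adjusted over the list alone. In fibrillar matrix and matrix enzymes (26 measured, median -0.15, adjusted p = 0.0532) Thbs1 fell, with 1 lower adjusted over the list alone, and the collagen Col5a1 stood at 107.1 ± 6.34 and 81.3 ± 7.91. In neuronal genes (15 measured, median -0.28, adjusted p = 0.632) Sema3c rose, with 1 higher adjusted over the list alone. Of the 15 measured genes that earlier work reported as FOXP2 targets, 0 passed by limma over all genes and 1 was lower adjusted over the list alone (median -0.10, adjusted p = 0.343). No member passed over all genes in the mitotic cell cycle (22 measured, median -0.03, adjusted p = 0.895) or DNA replication lists (20 measured, median 0.09, adjusted p = 0.510). The same held for Notch (-0.56, 5 measured), Wnt (-0.14, 11), hedgehog (0.06, 8), growth factor and receptor (-0.10, 21), interferon (-0.14, 17), basement membrane (0.03, 12) and oxidative phosphorylation genes (0.03, 32), given as median and measured members. It also held for osteogenic and chondrogenic (-0.31, 11), adipogenic (0.15, 10), skeletal muscle (-0.40, 5), imprinted (-0.17, 9) and Hox genes (0.07, 9) and for blood and immune cell markers (-0.37, 5). Epithelial and endothelial markers had 2 measured members each, too few for the test, with medians of 0.11 and -0.47.

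With an estimated correlation 0 of the 13 called lists passed, and fry called 5: smooth muscle, TGF-beta, mesenchymal, YAP/TEAD and histone genes. Camera calls were lost for proteases without vector (adjusted p = 0.0897), FOXP2 clone 2 (0.0526) or FOXP2 clone 4 (0.193) under quantile normalization (0.0502) and with joined rows (0.0813); for ribosomal proteins without the parental library (0.142) and under quantile normalization (0.312); for p53 targets without FOXP2 clone 2 (0.0683); for cytokines without FOXP2 clone 2 (0.0551) or FOXP2 clone 4 (0.0959); and for MAPK feedback (0.0506) and stress genes (0.0511) without FOXP2 clone 4. Without the 3 libraries whose mitochondrial rows were at 0, the calls of proteases (0.326), cytokines (0.668) and stress genes (0.249) were lost. Medians also moved by over 1.5 times when libraries were left out. That of ribosomal proteins was -0.04 without the parental library (-0.19 without vector); that of p53 targets was -0.10 without FOXP2 clone 3; that of NRF2 targets was -0.31 without FOXP2 clone 3; that of proteases was -0.26 without FOXP2 clone 3 and 0.02 without FOXP2 clone 4. For MAPK feedback it was -0.44 and -0.36 and for stress genes 0.19 and 0.51 without FOXP2 clones 2 and 3. Without the 3 libraries with mitochondrial rows at 0, medians were -0.33 for p53 targets, 0.14 for proteases, -0.40 for TGF-beta, -0.84 for MAPK feedback, -0.19 for cytokine and 0.12 for stress genes. The median, mean and camera direction differed in sign for 5 lists, basement membrane, hedgehog, neuronal, adipogenic and Hox genes.

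**Figure D3:**
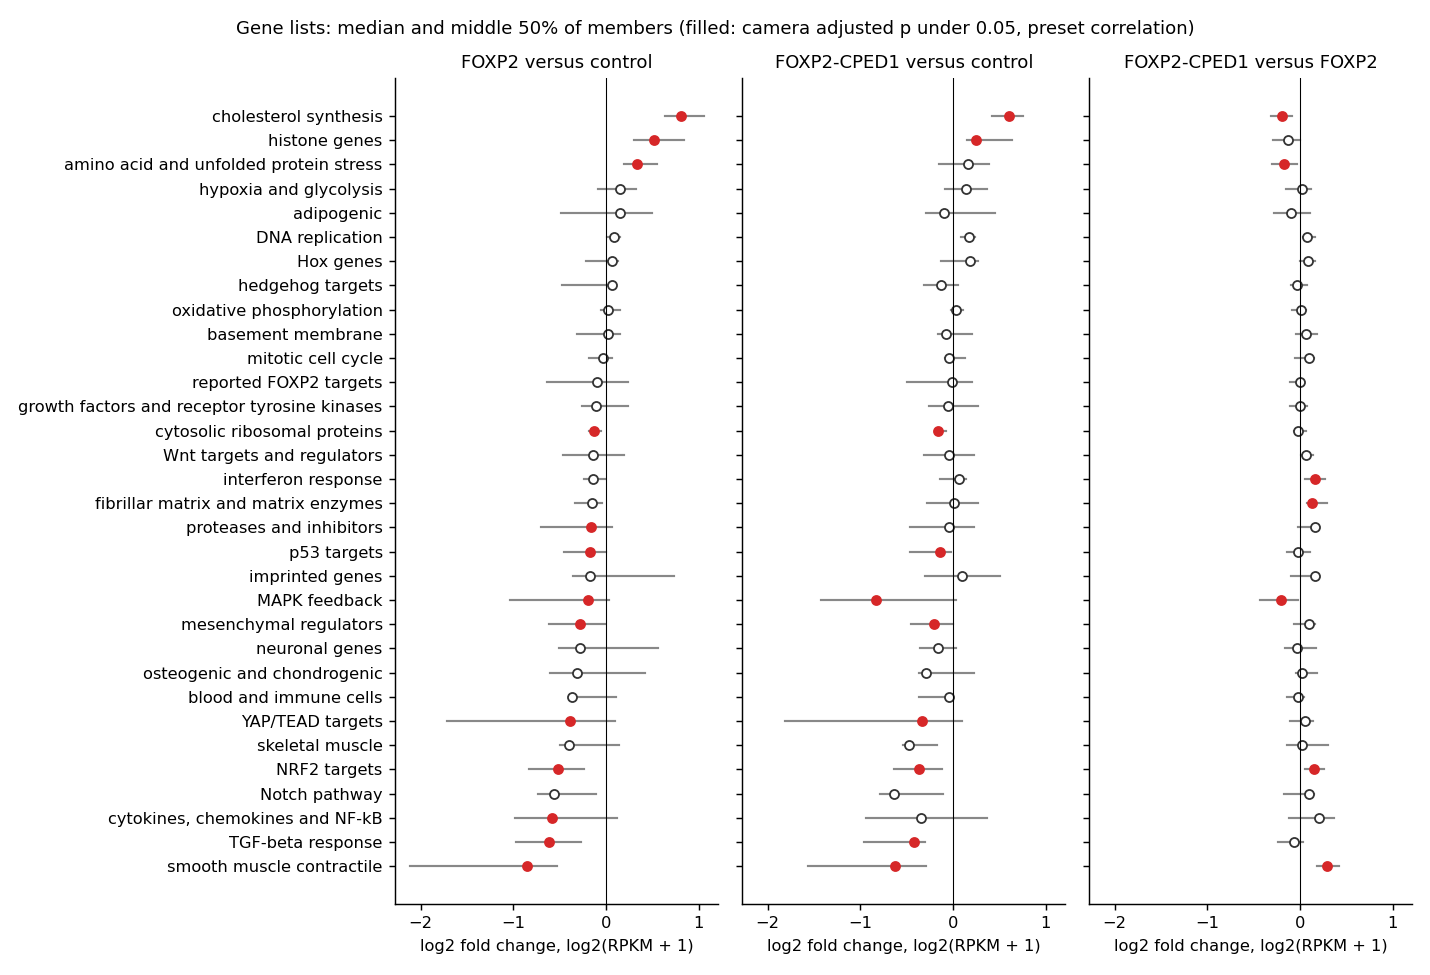
Median log2 fold change (dot) and middle 50% of members (line) for the 32 lists with enough members, on the log2(RPKM + 1) scale, in a panel per comparison; filled dots have a camera adjusted p under 0.05 with the preset correlation. Smooth muscle contractile genes are lowest with FOXP2 (-0.85) and cholesterol synthesis genes highest (0.82), and medians between the constructs lie between -0.20 and 0.29.

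The next comparison asked what FOXP2-CPED1 changes against the same control. Again most genes past the threshold were lower: 42 fell and 3 rose. Several of the falls were in transcription factors. The nuclear receptor Nr4a1 went from 315.8 ± 1.79 RPKM (SD, n = 2) to 21.4 ± 4.52 (n = 4), Egr1 from 176.9 ± 3.74 to 29.7 ± 9.65, Egr2 to 3.73 ± 1.66 and Egr3 to 3.02 ± 1.38. Fosb, a subunit of the transcription factor AP-1, went from 28.5 ± 0.614 to 3.32 ± 1.27 RPKM. Cpa6 rose from 0.175 ± 0.101 to 5.61 ± 1.51.

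The log2 fold change was -3.85 ± 0.52 for Nr4a1 (adjusted p = 0.0173, limma), -3.79 ± 0.57 for Egr3 (adjusted p = 0.0272), -3.42 ± 0.41 for Egr2 (adjusted p = 0.00828), -2.83 ± 0.40 for Fosb (adjusted p = 0.0197) and -2.59 ± 0.38 for Egr1 (adjusted p = 0.0247). Npas4 fell to 1.01 ± 0.146 RPKM and Arc to 1.07 ± 0.269, both with adjusted p = 0.00594. Phlda1, a cytoplasmic protein with a pleckstrin homology-like domain, fell from 75.5 ± 3.78 to 12.8 ± 3.82 RPKM (adjusted p = 0.0313), and F3 to 83.5 ± 22.1 (adjusted p = 0.0250). Foxn3 fell to 5.95 ± 1.05 RPKM (adjusted p = 0.0494). Each of these 10 genes was lower in 4 of 4 clones than in either control, again as the rule for named genes requires. Besides Cpa6 (log2 fold change 2.47 ± 0.29, adjusted p = 0.00828), Cbx2, a subunit of Polycomb repressive complexes, rose from 3.47 ± 0.187 to 8.62 ± 1.56 RPKM (adjusted p = 0.0313). The remaining riser, Gm16867, was named after its values were seen. Sema3c stood at 53.1 ± 9.59 (adjusted p = 0.0506), the tRNA-modifying enzyme Trit1 at 18.0 ± 2.85 against 8.94 ± 0.950 in the control (adjusted p = 0.067) and the ephrin Efna1 at 13.6 ± 2.15 against 6.21 ± 0.648 (adjusted p = 0.0986), all short of the threshold.

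In all, 45 of 12842 genes passed, 44 of them by at least 2-fold. An unadjusted p under 0.05 was reached by 935 genes, where chance gives 642 on average, again no firm bound. Values of the arms did not overlap for 25.6% of genes, against 13.3% if the libraries were interchangeable. With 2 controls so alike, that share too could be exceeded without any change. Among the 45 were 2 joined rows and 4 rows of symbols with several rows. The count was 0 without the parental library (limma; 408 at an unadjusted p under 0.05), 2 without vector, and 13, 14 and 17 without FOXP2-CPED1 clone 1, FOXP2-CPED1 clone 2 and FOXP2-CPED1 clone 3; without the parental library the log2 fold changes were still -3.84 for Nr4a1 and -3.48 for Egr2, but -1.88 for Foxn3, against -3.03. The count was 28 with a pseudocount of 0.1 and 929 with library quality weights, which put 343 higher and 586 lower.

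The same 4 lists, and MAPK feedback genes, were called lower with FOXP2-CPED1 with the preset correlation, and these calls were lost with an estimated correlation (smallest adjusted p = 0.130). Of 14 smooth muscle contractile genes, Lmod1 fell, to 0.201 ± 0.132 RPKM, 13 did not pass, and all 14 had negative log2 fold changes (median -0.62); Myl9 stood at 8.26 ± 4.38. The list was called (camera adjusted p = 1.40e-07; adjusted p = 0.217 with an estimated correlation), with 3 lower adjusted over the list alone. Of 21 TGF-beta response genes, Tgfb1i1 fell, to 31.3 ± 1.26 RPKM. Their median was -0.42 (adjusted p = 3.79e-07; adjusted p = 0.130 with an estimated correlation) and 6 were lower adjusted over the list alone; Ctgf stood at 29.5 ± 28.6. Of 16 YAP/TEAD targets, F3 fell, and the matrix protein Cyr61 stood at 120.3 ± 72.5 against 737.5 ± 8.93 in the control (adjusted p = 0.0506). Their median was -0.34 (adjusted p = 3.91e-05; adjusted p = 0.217 with an estimated correlation) and 7 were lower adjusted over the list alone. Of 19 MAPK feedback genes, Egr1 and Phlda1 fell, with a median of -0.83 (adjusted p = 5.90e-05; adjusted p = 0.514 with an estimated correlation) and 5 lower adjusted over the list alone; the receptor signalling inhibitor Spry2 stood at 7.94 ± 2.28 against 19.8 ± 0.299. Of 18 mesenchymal regulators, Itga5 fell, to 57.9 ± 2.68 RPKM (median -0.20, adjusted p = 0.0224; adjusted p = 0.217 with an estimated correlation), with 1 lower adjusted over the list alone.

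Cholesterol synthesis genes were again called higher with the preset correlation (adjusted p = 2.71e-10) but not with an estimated correlation (adjusted p = 0.360), with 18 of 19 log2 fold changes positive (median 0.60). By limma 0 passed singly over all genes and 1 was higher adjusted over the list alone; Cyp51 stood at 101.6 ± 27.7 against 43.6 ± 0.690 RPKM in the control and the squalene epoxidase Sqle at 74.8 ± 13.6 against 36.1 ± 1.33. Of 12 histone genes, 10 were on the higher side (median 0.25; adjusted p = 0.00783; adjusted p = 0.217 with an estimated correlation), with 2 higher adjusted over the list alone. NRF2 targets had a median of -0.36 (adjusted p = 0.00275; adjusted p = 0.655 with an estimated correlation), with 0 passing adjusted over the list alone; Hmox1 stood at 85.3 ± 16.2. The p53 targets had a median of -0.14 (adjusted p = 0.0181; adjusted p = 0.655 with an estimated correlation) and 1 lower adjusted over the list alone; Btg2 stood at 8.86 ± 5.32 RPKM (adjusted p = 0.067). Ribosomal protein genes had a median of -0.16 (adjusted p = 0.00678; adjusted p = 0.711 with an estimated correlation), with 0 passing adjusted over the list alone.

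The other 22 lists were not called (smallest adjusted p 0.126, Notch genes), with medians from -0.63 to 0.18. Among them Adm fell to 29.6 ± 3.18 RPKM and Slc2a1 to 52.3 ± 5.76, both in hypoxia and glycolysis (24 measured, adjusted p = 0.557), where 2 were lower adjusted over the list alone. Of 15 reported FOXP2 targets 0 passed by limma over all genes, 1 was lower adjusted over the list alone, and the adjusted p was 0.444. The stress genes, called higher with FOXP2, had a median of 0.16 here (adjusted p = 0.280), and the mitotic cell cycle genes one of -0.04 (adjusted p = 0.744). With an estimated correlation 0 of the 10 called lists passed, and fry called 4: TGF-beta, smooth muscle, YAP/TEAD and mesenchymal genes. Camera calls were lost for ribosomal proteins without the parental library (adjusted p = 0.201), FOXP2-CPED1 clone 1 (0.0510) or FOXP2-CPED1 clone 3 (0.103), under quantile normalization (0.147) and without the 3 libraries with mitochondrial rows at 0 (0.113); for histone genes without vector (0.121) or FOXP2-CPED1 clone 2 (0.0605) and with joined rows (0.0548); for p53 targets without FOXP2-CPED1 clone 2 (0.0720), FOXP2-CPED1 clone 3 (0.112) or those 3 libraries (0.0905); and for mesenchymal regulators without FOXP2-CPED1 clone 2 (0.0564) or FOXP2-CPED1 clone 4 (0.0882). Medians moved by over 1.5 times for ribosomal proteins without the parental library (-0.07; -0.21 without vector) and FOXP2-CPED1 clone 2 (-0.26), for histone genes without the parental library (0.50) and FOXP2-CPED1 clone 4 (0.40), and for p53 targets without the parental library (-0.25) and FOXP2-CPED1 clones 1 (-0.08), 2 (-0.07) and 4 (-0.40). Signs of median, mean and camera direction differed for 5 lists, mitotic cell cycle, fibrillar matrix, basement membrane, growth factors and imprinted genes.

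The differences of the clones of both constructs from the control ran the same way for most genes. Differences that all clones share may come from the constructs or from the derivation or handling of clones, which cannot be told apart here. Among the genes called in both comparisons, 37 fell and 2 rose, including Nr4a1, Egr2, Egr3, Npas4, Arc, F3, Adm, Lmod1, Tgfb1i1, Itga5 and Slc2a1 among the falls and Cpa6 and Gm16867 as the rises. In simulated data with no change in any group, 0 and 0 called genes were shared. All 10 libraries there were random draws, with the drawn controls shared by both comparisons. Few or no genes pass in such data, so these values of 0 say little. Independent lists of the sizes called would share 0.167 and 0.00117. Across 12842 genes, which are not independent replicates, the log2 fold changes correlated with Pearson's r = 0.826. The simulated groups gave 0.664 (0.612 to 0.722 over 100 draws). Genes were drawn independently there, so this range may be too narrow for real libraries. All libraries were also drawn with the same spread per gene. The real controls differed less from each other (root mean square log2 difference 0.418) than clones of a construct did (means 0.657 and 0.580). The simulated values, also those with 1 control left out, may therefore be too high for these controls. The covariance was 0.150 against 0.0728 simulated, a difference of 0.0773, and 81.5% of genes had the same sign against 73.2%. That difference was 0.0503 without the parental library (r = 0.867 against 0.8 simulated, 0.760 to 0.831) and 0.0280 without vector (r = 0.852 against the same simulated values). The 2 controls cannot be split into parts that keep 2 libraries each, so part of the excess may come from the shared controls. Without the 3 libraries with mitochondrial rows at 0 the correlation was 0.668, against 0.546 simulated for that design (0.488 to 0.606), and the covariance was 0.134 against 0.0559, a difference of 0.0782.

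**Figure D4:**
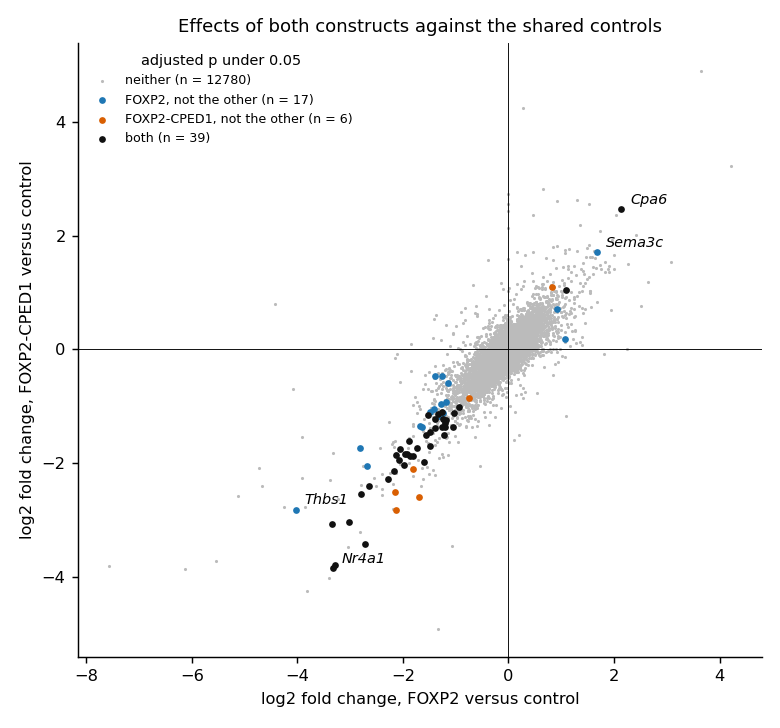
Log2 fold change on the log2(RPKM + 1) scale with FOXP2 (x axis) and with FOXP2-CPED1 (y axis) against the same 2 controls, with a point per gene, coloured by the comparison in which its adjusted p was under 0.05. Of the genes that passed in both comparisons, 37 lie lower and 2 higher than in the controls on both axes.

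The direct comparison asked where FOXP2-CPED1 differs from FOXP2. By limma 0 of 12842 genes passed (smallest adjusted p 0.614). An unadjusted p under 0.05 was reached by 278 genes, 135 of them higher and 143 lower with FOXP2-CPED1. Chance gives 642 on average, but splits of the clones that mix the constructs gave 136 to 2989. The gene with the smallest p was the hydrolase gene Abhd14a, at 5.09 ± 1.32 RPKM with FOXP2 and 15.2 ± 3.22 with FOXP2-CPED1 (SD, n = 4 each), and at 11.3 ± 4.07 in the control. Its log2 difference was 1.42 ± 0.22, with no overlap between the clones. The adaptor Nck2 stood at 22.3 ± 4.14 and 10.5 ± 2.93 RPKM, a log2 difference of -1.04 ± 0.20 (adjusted p = 0.741).

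Other genes with small p were also short of the threshold. On the higher side with FOXP2-CPED1 were Amotl2 (88.1 ± 15.8 RPKM with FOXP2 and 128.2 ± 12.5 with FOXP2-CPED1), the joined row BC023719/A930015D03Rik (2.06 ± 0.362 and 4.24 ± 0.706) and the ribosomal pseudogenes Rps19-ps6 (164.0 ± 18.2 and 289.5 ± 58.5) and Rpsa-ps10 (1854 ± 235.1 and 3172 ± 678.4), which can share reads with their parent genes. On the lower side were the noncoding RNA Crnde (2.95 ± 0.775 and 1.58 ± 0.186), Ott (23.0 ± 1.58 and 17.6 ± 1.31), the tetraspanin Tspan5 (47.6 ± 2.22 and 35.9 ± 4.40) and the transcription factor Tfec (2.28 ± 2.26 and 0.137 ± 0.160). Arms did not overlap for 1.37% of genes, against 2.86% by chance. Leaving out FOXP2-CPED1 clone 2 gave 1 gene, Gm12079, and library quality weights gave 4, BC023719/A930015D03Rik, a further row of Gm7665, Gm10033/Gm10311 and Abhd14a, of which the genes outside the rule were named after their values were seen.

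Several lists leaned one way between the constructs although no member passed. All 14 smooth muscle contractile genes were on the higher side with FOXP2-CPED1 (median 0.29), such as Myl9 at 3.20 ± 1.37 RPKM with FOXP2 and 8.26 ± 4.38 with FOXP2-CPED1. The list was called (camera adjusted p = 1.65e-05; adjusted p = 0.729 with an estimated correlation). Of 26 fibrillar matrix genes 23 were on the higher side (median 0.13, adjusted p = 0.000784; adjusted p = 0.729 with an estimated correlation); the crosslinking enzyme Lox stood at 681.5 ± 124.8 and 835.7 ± 76.8 and the collagen Col1a1 at 1009 ± 129.3 and 1180.2 ± 67.6. Interferon response genes had 16 of 17 on the higher side (median 0.17, adjusted p = 0.00432; adjusted p = 0.729 with an estimated correlation), with the antiviral factor Xaf1 at 8.22 ± 3.18 and 10.9 ± 1.41. NRF2 targets had 13 of 16 on the higher side (median 0.15, adjusted p = 0.0202; adjusted p = 0.797 with an estimated correlation), with the glutathione transferase Gsta4 at 90.1 ± 53.4 and 124.5 ± 30.2. Cholesterol synthesis genes had all 19 on the lower side (median -0.19, adjusted p = 0.000726; adjusted p = 0.797 with an estimated correlation), with Nsdhl at 16.6 ± 4.46 and 11.5 ± 1.37. MAPK feedback genes had 15 of 19 on the lower side (median -0.20, adjusted p = 0.0202; adjusted p = 0.797 with an estimated correlation), with Egr1 at 57.7 ± 20.5 and 29.7 ± 9.65. Stress genes had 21 of 24 on the lower side (median -0.18, adjusted p = 0.0202; adjusted p = 0.729 with an estimated correlation), with the membrane protein gene Herpud1 at 77.9 ± 21.3 and 59.6 ± 7.98.

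In each of these 7 lists 0 members passed by limma, over all genes or adjusted over the list alone, and 0 were called by fry (adjusted p = 0.972). The other 25 lists were not called (smallest adjusted p 0.0699, cytokines), with medians from -0.12 to 0.21; YAP/TEAD targets had 1 member higher adjusted over the list alone. Reported FOXP2 targets had a median of 0.00 (adjusted p = 0.952). Signs of median, mean and camera direction differed for 6 lists, YAP/TEAD, hypoxia, reported FOXP2 targets, skeletal muscle, ribosomal and oxidative phosphorylation genes. Each of the 7 calls was lost without some clone: smooth muscle without FOXP2 clone 3 (adjusted p = 0.0535); cholesterol without FOXP2 clone 1 (0.123); matrix without FOXP2 clone 2 (0.415) or FOXP2-CPED1 clone 2 (0.0998); interferon without FOXP2 clone 2 (0.867); NRF2 without FOXP2 clone 3 (0.997), FOXP2 clone 4 (0.0902), FOXP2-CPED1 clone 2 (0.0998) or FOXP2-CPED1 clone 4 (0.268); MAPK without FOXP2 clone 2 (0.850, with the direction turned), FOXP2 clone 3 (0.0535), FOXP2-CPED1 clone 2 (0.177) or FOXP2-CPED1 clone 3 (0.161); and stress without FOXP2 clone 2 (0.415), FOXP2 clone 4 (0.152), FOXP2-CPED1 clone 1 (0.0520), FOXP2-CPED1 clone 2 (0.0998) or FOXP2-CPED1 clone 3 (0.157). Without the 3 libraries with mitochondrial rows at 0, matrix (0.781), interferon (0.260) and stress genes (0.781) turned direction, and the calls of MAPK (0.781) and cholesterol genes (0.0673) were lost. The medians moved by over 1.5 times as well. The smooth muscle median was 0.15 without FOXP2 clone 3 and 0.14 without FOXP2-CPED1 clone 4, and the cholesterol median -0.09 without FOXP2 clone 1, -0.38 without FOXP2 clone 3 and -0.34 without FOXP2-CPED1 clone 3. The matrix median was 0.03 and 0.29 without FOXP2 clones 2 and 3 and 0.03 and 0.36 without FOXP2-CPED1 clones 2 and 4. The interferon median was 0.05 and 0.30 without FOXP2 clones 2 and 3. The NRF2 median was 0.24, 0.01 and 0.08 without FOXP2 clones 2, 3 and 4 and 0.10 without FOXP2-CPED1 clone 2. For MAPK genes it was 0.00 without FOXP2 clone 2 and -0.11, -0.08 and -0.42 without FOXP2-CPED1 clones 2, 3 and 4. For stress genes it was -0.07, -0.28 and -0.12 without FOXP2 clones 2, 3 and 4 and -0.10 and -0.28 without FOXP2-CPED1 clones 3 and 4. Without the 3 libraries the medians were 0.55 (smooth muscle), -0.06 (matrix), -0.15 (interferon), 0.36 (NRF2), -0.03 (MAPK) and 0.11 (stress).

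The clones of each construct also differed among themselves. The mean root mean square log2 difference over tested genes was 0.657 over the 6 pairs of FOXP2 clones and 0.580 over the 6 pairs of FOXP2-CPED1 clones. The difference of 0.0765 was not past the threshold (exact two-sided permutation over the 35 splits of the clones, p = 0.4, smallest possible 0.0286). The same distance was 0.418 between parent and vector, 0.592 between clones of different constructs and 0.608 between clones and controls.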

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

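The checks on mitochondrial rows in this part were chosen after the zeros had been seen.

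Of 234 groups of 4 clones examined, 14 had a library far from the other 3, where chance alone gives 11.7, so single cases carry little weight. In FOXP2-CPED1 clone 4, 4 genes stood apart. Thbs1 was at 12.1 RPKM (others 28.2 to 29.8), F3 at 50.7 (91.8 to 98.9) and the chaperone Dnajb9 at 3.45 (5.03 to 5.32), all below the other clones, and Plau at 17.9 (4.60 to 5.69) lay above them. In FOXP2 clone 2, Npas4 was at 1.62 RPKM (others 0.376 to 0.532), Dusp5 at 43.6 (10.1 to 12.9) and the prostaglandin synthase Ptgs2 at 62.3 (23.5 to 25.8). In FOXP2-CPED1 clone 3, the sterol synthesis enzyme Lss was at 20.5 (13.7 to 14.4), the sterol carrier Stard4 at 19.7 (12.6 to 13.2) and Arc at 0.673 (1.16 to 1.27). The remaining genes were Fas, a death receptor, at 21.6 in FOXP2-CPED1 clone 2 (12.4 to 12.9), the NF-kB subunit Relb at 20.3 in FOXP2 clone 3 (10.04 to 11.09) and the integrin Itgb3 at 4.01 in FOXP2-CPED1 clone 1 (6.49 to 6.96). The summed RPKM of rows that name a gene, without mitochondrial rows, was 895800 in FOXP2 clone 2 and 772700 to 779200 in the other FOXP2 clones. Of 1454 unnamed rows that passed the filter, limma called 0 higher in either construct, 4 lower with FOXP2 and 3 lower with FOXP2-CPED1.

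Both mitochondrial rows were listed at 0 in FOXP2 clone 2, FOXP2 clone 4 and FOXP2-CPED1 clone 3, and summed to 33213 to 41130 RPKM elsewhere. The 6 rows of nuclear copies of mitochondrial sequence summed to 24415 to 34293 RPKM across the 10 libraries. Their median in the 3 libraries was 1.09 times that in the other 7, which argues against a loss of mitochondrial RNA in those cells. That the mitochondrial chromosome was left out when these libraries were processed stays open, since 0 mitochondrial rows were above 0 in the 3 libraries, a value from which this explanation was drawn. No other biological explanation was tested.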

How the results depend on the processing

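Leaving out the 3 libraries with mitochondrial rows at 0, and the comparison of all 8 clones with the control, were chosen after seeing the data, as were the settings that change which rows enter. Over single-library removals, results of named genes, called or not, kept direction and side of the threshold 1494 times. They gained a call 15 times and lost it 151 times. Most of those kept were of genes not called in the main fit, where only 36 results were calls. Over other settings these counts were 1850, 82 and 59, with 3 reversals. The lists called by camera kept their calls 264 times, lost 35 and turned 1 when libraries were removed, and over other settings 181, 63 and 3. Main results stayed within their bounds 69 times and moved 21 times over removals, and 87 and 17 times over other settings. Unless a sentence gives it, the cause was not tested.

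The controls limit the results most. Without 1 of them the lone control is assumed to vary like the other groups. Of 36 calls of named genes against the control, 0 held without parent and 2 without vector, both of Foxn3, although the log2 fold changes of the others stayed at 90.1% to 104% and 95.9% to 110% of their value (Foxn3 62.2% and 138%); 23, 31, 30 and 26 held without FOXP2 clones 1 to 4, 20, 22, 23 and 32 without FOXP2-CPED1 clones 1 to 4, and 21 without the 3 libraries. Calls that no removal of a clone ended were those of Adm, Arc, Cpa6, Itga5, Lmod1, Npas4 and Tgfb1i1 in both constructs, of F3 and Thbs1 with FOXP2, and of Egr2 with FOXP2-CPED1.

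Over single removals, genes called with FOXP2 ranged from 2 (without parent; 577 at an unadjusted p under 0.05) to 64, with 3 without vector, 22 and 25 without FOXP2 clone 1 and FOXP2 clone 4, and 33 and 29 without FOXP2-CPED1 clone 1 and FOXP2-CPED1 clone 3. With FOXP2-CPED1 they ranged from 0 (without parent, limma; 408 unadjusted) to 57, with 2 without vector and 13, 14 and 17 without FOXP2-CPED1 clones 1, 2 and 3. Between constructs the range was 0 to 1 (without FOXP2-CPED1 clone 2), and for all 8 clones 11 (without parent) to 97, with 13 without vector, 58 without FOXP2 clone 1 and 52 without FOXP2-CPED1 clone 3. The agreement of the effects against control, as Pearson's r across genes, ran from 0.748 (without FOXP2 clone 3; 0.631 simulated with no effect) to 0.867 (without parent; 0.8 simulated). The difference in the spread between clones ran from 0.0246 (without FOXP2 clone 2) to 0.161 (without FOXP2-CPED1 clone 4). Camera called 9 to 17 lists with FOXP2, 7 to 10 with FOXP2-CPED1 and 5 to 10 between constructs. The list MAPK feedback, FOXP2-CPED1 versus FOXP2, had p from 5.47e-07 (without FOXP2 clone 4) to 0.764 (without FOXP2 clone 2, turned).

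With a pseudocount of 0.1, which gives low values more weight by construction, 37 genes passed with FOXP2 and 28 with FOXP2-CPED1, and 563 genes instead of 296 differed at least 2-fold for vector versus parent. Library quality weights gave 2095 genes with FOXP2 (1013 higher, 1082 lower), 929 with FOXP2-CPED1 (343 and 586), 1136 in all clones (458 and 678) and 4 between constructs, and turned Gsta4 (-0.21) and Nqo1 (-0.12) between constructs; they ranged from 0.196 for FOXP2 clone 2 to 6.62 for FOXP2 clone 1. Fitting only the arms compared gave 9 genes with FOXP2 and 65 with FOXP2-CPED1. Without the 3 libraries 23 genes passed with FOXP2 and 43 in all clones, and the correlation of effects was 0.668; between constructs Trib3 (0.10) and the matrix (p = 0.498), interferon (p = 0.0732) and stress lists (p = 0.581) turned. With an estimated correlation camera called 0, 0 and 0 lists (between constructs, FOXP2, FOXP2-CPED1), against 7, 13 and 10 with the preset one, and fry 0, 5 and 4. Neither Foxp2 nor Cped1 was called without the filter, under the pseudocounts of 1 and 0.1 or either scaling.

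No paired analysis was possible for the comparisons with the control because the control libraries carry no clone number. Between constructs, a replicate block on clone number gave 0 genes by limma and 8 lists, and deviations of same-numbered clones correlated at -0.0357, -0.24, 0.281 and 0.166, so the numbers do not pair the clones. Depth is known only relative to the parental library, so low values carry an unknown counting error.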

Other observations

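In this part, the lists of immediate-early genes and of SRF and MRTF targets, the comparison of all 8 clones with the control, the tests of scaling and of vector against parent, the reassignment of genes to chromosomes and the splits for the 0 called genes were chosen after the results were seen. The genes around Foxp2 and the genes named here were too.

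As a list, immediate-early genes, which cells switch on within minutes of a growth signal, were lower in the clones of both constructs. Of 29 measured, 5 fell with FOXP2 (median log2 fold change -0.97) and 13 were lower adjusted over the list alone (camera adjusted p = 0.00401 with an estimated correlation). With FOXP2-CPED1 7 fell (median -1.21) and 20 were lower adjusted over the list alone (adjusted p = 0.00287 with an estimated correlation). All 29 log2 fold changes were negative with FOXP2, and 27 were with FOXP2-CPED1, but their sizes differed. Fos, a gene of this kind, stood at 14.2 ± 0.366 RPKM (SD, n = 2) in the control. It stood at 15.4 ± 9.14 with FOXP2 and 7.95 ± 3.17 with FOXP2-CPED1 (n = 4 each). Targets of the actin-responsive factors SRF and MRTF, 33 measured, were lower too: 9 fell with FOXP2 (median -0.89, 22 adjusted over the list alone, adjusted p = 0.00401 with an estimated correlation) and 6 with FOXP2-CPED1 (median -0.66, 13 adjusted over the list alone, adjusted p = 0.00767 with an estimated correlation). Srf itself went from 53.4 ± 4.32 RPKM in the control (SD, n = 2) to 13.0 ± 2.83 with FOXP2 and 12.3 ± 2.05 with FOXP2-CPED1 (n = 4 each). Both lists were drawn up after the called genes were seen and hold several of them, so their p-values are not independent evidence. Their camera p-values, here and between the constructs, were adjusted over these 2 lists only, apart from the fixed lists. That adjustment is milder than the one for the fixed lists. Passing with an estimated correlation therefore does not set these lists above the fixed lists, whose calls were lost with it. In single clones the medians ran from -1.38 to -0.80 for immediate-early genes and from -1.23 to -0.28 for SRF and MRTF targets, with the smallest fall in FOXP2-CPED1 clone 4 for both. Between the constructs the medians were -0.34 for immediate-early genes and 0.18 for SRF and MRTF targets. Camera called both lists with the preset correlation (adjusted p = 8.55e-06 and 1.60e-08), with adjusted p = 0.0927 for both with an estimated correlation and 0 members past the threshold by limma over all genes or adjusted over the list alone. These medians were -0.22 without FOXP2-CPED1 clone 3 and -0.51 without FOXP2-CPED1 clone 4 for the first list, 0.09 without FOXP2 clone 3 and 0.07 without FOXP2-CPED1 clone 4 for the other, and -0.08 and 0.39 without the 3 libraries with mitochondrial rows at 0.

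With all 8 clones against the control, 82 genes fell and 12 rose by limma, with 1253 at an unadjusted p under 0.05; 51 of the 94 were also called with FOXP2 and 44 with FOXP2-CPED1. Among the falls were Srf (log2 fold change -2.01, adjusted p = 0.000698), Fosb (-2.48, adjusted p = 0.0239), the phosphatase Dusp5 (-2.42, adjusted p = 0.0276) and the matrix protein Cyr61 (-2.49, adjusted p = 0.0414). Among the rises were Cpa6 (2.30, adjusted p = 0.00389), the ephrin Efna1 (1.01, adjusted p = 0.0276) and the sterol demethylase Cyp51 (1.26, adjusted p = 0.0429). The count was 11 without parent, 13 without vector, 58 without FOXP2 clone 1, 52 without FOXP2-CPED1 clone 3 and 43 without the 3 libraries with mitochondrial rows at 0. Of the 45 ways to choose 2 of the 10 libraries, 2 gave as many genes, the controls with 94 and another pair with 2156, and a further pair, vector with FOXP2-CPED1 clone 4, gave 82. That share is just under 0.05, but the comparison was chosen after the results were seen, and parent and vector were the most alike pair of libraries (Spearman's rho 0.982), so chance is not taken as excluded for the count. The pair with 2156, FOXP2 clone 2 with FOXP2-CPED1 clone 4, points to a structure of the samples: their deviations from the means of their constructs correlated at 0.393 across genes, and they lay at -32.4 and -39.3 on the first principal component.

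Scaling of the libraries is argued against as the source of the lower immediate-early genes, since their median in the 8 clones was -1.21 under both quantile and median-ratio scaling. Fewer dividing cells are argued against too: the 42 mitotic cell cycle and DNA replication genes had a median of 0.0746, with quartiles of -0.0453 and 0.147. Derivation or handling of the clones apart from the controls cannot be told apart from the constructs. Vector and parental cells differed by a median of -0.0146 in this list, but no control is stated to be a clone. An effect that both constructs share may also lie behind the pattern, and that was not tested.

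Some clones differed over whole chromosomes from the median of all libraries, taken gene by gene, with each library then centred on its own median. The largest median shift among 9618 genes on 20 chromosomes was 0.215 on the log2 scale, for the 478 genes of chromosome 6 in FOXP2 clone 4, while 0% of 1000 random reassignments of genes reached it (largest 0.108), which argues against chance. Trends with GC content, length and level are argued against for this shift, since 104.6% of the shift was kept without them, as are a few strong genes, since 76.4% of the genes lay on its side and the first and second parts of the chromosome gave 0.222 and 0.209. In all, 22 pairs of library and chromosome lay beyond 0.0772, the 95th percentile of the draws, among them chromosome 9 in FOXP2 clone 4 (-0.193), chromosome 14 in FOXP2 clone 3 (0.178) and 4 in the parental and vector libraries. Once the trends were removed 18 of the 22 were still beyond it, and 4 were not: chromosome 19 in FOXP2 clone 2 (0.0800 before and 0.0274 after), parent (0.0946 and 0.0689) and vector (0.0791 and 0.0705), and chromosome X in FOXP2-CPED1 clone 1 (-0.0838 and -0.0657). A further 7 passed the same bound only after the removal: chromosomes 1 (0.0734 before and 0.0772 after, before rounding just beyond it), 4 (0.0347 and 0.0848), 8 (0.0236 and 0.0774) and 17 (0.00511 and 0.0773) in FOXP2 clone 4, chromosomes 5 (0.0605 and 0.0824) and 11 (0.0655 and 0.0860) in FOXP2-CPED1 clone 1, and chromosome 11 in parent (-0.0310 and -0.0850). Shifts beyond the bound before this removal recurred on chromosomes 14 and 19. Chromosome 14 was higher in FOXP2 clone 3 and FOXP2-CPED1 clones 1 (0.166) and 3 (0.127). It was lower in FOXP2 clone 4 (-0.111), parent (-0.0958) and vector (-0.0915). Chromosome 19 was lower in FOXP2-CPED1 clones 1 (-0.175), 3 (-0.103) and 4 (-0.0866), and higher in FOXP2 clone 2, parent and vector. A candidate explanation is a change in chromosome copies in 1 or more cultures, a hypothesis that was not tested here.

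In the wider region around Foxp2, some genes were higher in FOXP2 clone 4 than in the other libraries and others were not. These genes were chosen by hand, leave out others in the region and need not lie next to Foxp2. In FOXP2 clone 4, Foxp2 itself was at 1.02 RPKM. Cttnbp2, a cortactin-binding protein, was at 4.24 RPKM there and at most 0.0372 in the other 9 libraries. Tfec, a transcription factor, was at 5.58 RPKM and at most 1.61 in the others, and Mdfic, an inhibitor of MyoD family proteins, at 44.8 against 22.1 to 29.0, while the receptor Met was at 23.5 against 11.2 to 21.2. The membrane protein genes Cav1 (318 RPKM, 284 to 542 in the others) and Cav2 (34.9, 19.6 to 41.7 in the others) and the focal adhesion gene Tes (29.3, 19.4 to 60.5 in the others) lay within the range of the other libraries.

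Other splits of the clones were set against the direct comparison of the constructs. By limma the real split called 0 genes, which all 35 of the 35 splits into 4 and 4 reach by construction (highest 9), so this count of splits decides nothing. At an unadjusted p under 0.05 the real split gave 278 genes and 25 of 35 splits gave as many, the highest 2989, a count that again points to a structure of the samples. Chance cannot be excluded for the 278 genes.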
